A study of Escherichia coli with 4 samples.

How the data were processed

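Ribosome-protected fragments of Escherichia coli MG1655 were measured in 2 WT and 2 ΔrpmE libraries. Per the labels' protocols, footprints were made with MNase, ribosomes were pelleted, and the RNA was ligated to a preadenylated linker, depleted of rRNA, reverse transcribed, circularised and amplified. Per the submitters' processing notes, CASAVA 1.8 and STAR 2.7.0a were used. The genome build, annotation, read lengths and the rule that places a footprint at a nucleotide are not given in the sources used here. MNase prefers certain bases, which blurs single-nucleotide positions, and the coding frame that held most footprints took 42.0% to 43.2% in every library, so positions were read by codon or by segment. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

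The deposited values are whole-number counts of footprints per nucleotide of each listed gene, from 50 nt before the start codon to 50 nt after the coding sequence. They were used as counts, with no normalization by the authors visible in them. The main peaks lay at the codon after the start codon and at the first nucleotide of the stop codon, as for footprints placed at the ribosomal A site. In each of the 4 libraries the sparsest listed gene had exactly 1 footprint per codon, and 0 listed genes had less, so a gene that is not listed in a library was taken to have had fewer footprints than codons there. Library totals are therefore sums over listed genes. Of 2266 locus tags listed in any library, 2264 matched the RefSeq table of assembly ASM584v2, which was used for symbols and neighbours only. As the build behind the counts is not named, no coordinates are given. Among the 1469 genes listed in all 4 libraries, 19 had another coding length than in that table and 9 were pseudogenes there. The genes tufA and tufB are near-identical, so their counts are uncertain.

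Footprints were summed over each ORF without its first 5 and last 5 codons for genes listed in all 4 libraries. The sums in the test ranged from 5282365 to 16599177 per library. Counts were scaled with TMM (factors 0.880 and 0.929 in WT, 1.14 and 1.08 in ΔrpmE) and tested with edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. The filterByExpr step removed 0 genes. The biological coefficient of variation was 16.5%. Standard errors are the log2 change divided by the square root of the F statistic. Gene lists, 28 in number, were tested with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation) and fry where at least 5 members were tested.

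For placement along ORFs, an early segment (codons 2 to 30) and a downstream segment (codon 51 to 5 codons before the stop) were counted in ORFs of at least 100 codons with at least 40 footprints in each segment over the 4 libraries. The segment by genotype interaction was tested with edgeR's quasi-likelihood test, with each library as a block. Metagene values are means over ORFs of density relative to the ORF's own mean from codon 51 on, for ORFs with at least 1 footprint per 3 codons there, compared by an exact two-sided permutation test over the 6 possible assignments. Per-library log2 ratios used a pseudocount of 0.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

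The genes named follow a rule fixed before the data were examined. It takes rpmE, ykgM and ykgO, the 10 largest rises and 10 largest falls at an adjusted p of 0.05 with non-overlapping groups and a mean of at least 50 counts, the 3 members with the smallest p in each list, and the 5 largest rises and falls of the segment ratio. Further list members given as examples, corA, phoP and genes with bounds were chosen after their values were seen. A bound sets a gene that is not listed in a library to the highest count the listing rule allows, and is a ratio of means of scaled counts over the whole ORF.

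The per-gene edgeR tests of occupancy and of the segment ratio were run on simulated data with 200 changed genes. Counts were drawn from the real means and library sizes, independently per library and with a single dispersion for all genes. The rates may therefore not hold for the real data. No such rates are given for camera, fry or the permutation test. For occupancy over 1469 genes, 26.9% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes were recovered, with 6 false calls. For the segment ratio over 1268 genes, 61.2%, 97.0% and 100% were recovered, with 8 false calls. Alternatives fixed before the data were examined were DESeq2 1.42.0, no scaling, other filters, ORF parts and segments, capped single positions, weighting by footprints, positions shifted by 1 codon, leaving out each library and the replicate number as a block. Amino acid and codon sequences were not used here, so the planned comparisons of ORFs rich in aspartate, glutamate and proline and of codon occupancy were not run.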

Results

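Ribosome profiling, in which the mRNA fragments protected by ribosomes are sequenced, was performed on the MG1655 strain of Escherichia coli with micrococcal nuclease (MNase) as the footprinting enzyme. The comparison was between the wild type (WT, 2 libraries) and a strain without rpmE (ΔrpmE, 2 libraries). The gene rpmE encodes bL31, a ribosomal protein of the large subunit that bridges to the small subunit, and the series title concerns how a nascent chain inside the exit tunnel stabilises the translating ribosome. The listed genes held 19718248 and 13878892 footprints in the WT libraries and 6045388 and 6299719 in the ΔrpmE libraries. These are sums over the genes listed for each library, which numbered 2215 and 2004 in WT and 1612 and 1545 in ΔrpmE, and not the full depth. Of the footprints, 94.7% and 94.6% lay in coding sequence in WT and 94.9% and 95.2% in ΔrpmE. The gene lpp, for the major outer membrane lipoprotein, took the largest share of coding footprints in every library, between 4.71% and 5.09%.

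The deleted gene was examined first. The rpmE coding sequence, of 71 codons, carried 47009 and 32420 footprints in the WT libraries. It carried 239 in ΔrpmE replicate 1, and it was not listed in ΔrpmE replicate 2, where the listing rule places it below 71 footprints. After scaling and without 5 codons at each end, WT density was 2668 ± 168 CPM (TMM-scaled footprint counts; SD, n = 2), which was 79.3-fold above the 33.6 CPM of ΔrpmE replicate 1. Because 1 library did not list it, rpmE was not in the tested set and has no p-value. The zinc-free paralog of bL31, ykgM, was listed with 131 and 94 footprints in WT and was not listed in either ΔrpmE library. The paralog of bL36 encoded beside it, ykgO, was listed in WT replicate 1 alone, with 49 footprints. Their absence shows no fall, since the listing limit for ykgM lies at 13.5 and 13.6 CPM in ΔrpmE, above the 8.33 and 7.95 CPM of WT, and ykgO lay near the limit in WT itself. The neighbours of rpmE that could be tested showed no change past the threshold, with log2 values of 0.13 ± 0.17 (SE) for cytR and 0.14 ± 0.16 for metJ in edgeR's quasi-likelihood test (adjusted p = 0.592 and 0.529).

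The first comparison asked which genes carried more or fewer ribosomes without bL31. Among the genes listed in all 4 libraries, the largest rises in ΔrpmE were in mgtS, suhB and ilvC, and the largest falls in tnaA, tnaC and ansB. Lists of ribosome assembly and branched-chain amino acid genes were higher, and lists of sugar use and glycolysis genes lower, by camera with a preset correlation between genes. None of the 4 passed with an estimated one (adjusted p = 0.966 for each with an estimated correlation). Of 1469 genes listed in all 4 libraries, 255 were higher and 244 lower in ΔrpmE in edgeR's quasi-likelihood test at an adjusted p of 0.05. Without scaling beyond library size the median of all genes lay at 0.28 on the log2 scale and the counts were 451 higher and 151 lower, so directions here are relative to the bulk of genes. The count fell from 499 to 290 without ΔrpmE replicate 1 and to 161 without ΔrpmE replicate 2. The WT libraries differed by over 2-fold from each other at 37 of these genes and the ΔrpmE libraries at 8. As no RNA libraries were analysed here, occupancy combines mRNA level and translation.

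Among tested genes that rose, mgtS, for a small membrane protein linked to magnesium retention, had the largest change. Its log2 value was 2.78 ± 0.24 (SE, adjusted p = 0.00347), from 41.2 ± 11.7 CPM in WT to 283.6 ± 18.2 in ΔrpmE (SD, n = 2 each; edgeR). It was followed by suhB, an inositol monophosphatase family protein with a role in rRNA transcription, at 2.56 ± 0.38, and by ilvC and ilvG of isoleucine and valine synthesis at 2.32 ± 0.25 and 2.14 ± 0.18. The ilvG entry is a pseudogene in the reference table, as the MG1655 copy carries a frameshift. The putrescine importer gene plaP rose by 2.12, pstB of the phosphate transporter by 2.06, hslJ by 1.97, the purine salvage gene gpt by 1.97, ytjA by 1.96 and cyoA of cytochrome bo oxidase by 1.95, all with adjusted p between 0.00356 and 0.0229. Without WT replicate 2 the rise was 3.06 for plaP and 2.61 for gpt. The magnesium channel gene corA, named after its values were seen, rose by 1.66 ± 0.18 (edgeR adjusted p = 0.004).

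The largest fall among tested genes was that of tnaA, which encodes tryptophanase. Its log2 value was -4.91 ± 0.45 (SE, adjusted p = 0.00347), or 30.2-fold lower, and the upstream leader tnaC fell by 3.95 ± 0.26 (edgeR). The ribosome-inactivating factor raiA fell by 3.14 ± 0.27, 8.84-fold, and was among the most heavily occupied of these genes in WT. Others were the periplasmic asparaginase gene ansB at -3.20 ± 0.70, glpC of anaerobic glycerol-3-phosphate dehydrogenase at -2.80, the sorbitol genes srlD and srlB at -2.75 and -2.64, the fumarate reductase genes frdD and frdB at -2.52 and -2.40, and the ribonucleoside hydrolase gene rihA at -2.47. The WT libraries themselves differed at ansB, with 3509 and 908.2 CPM, and its value was -1.93 without WT replicate 1, -3.87 without WT replicate 2 and -3.91 without ΔrpmE replicate 1. Without ΔrpmE replicate 1 the value of tnaA was -5.63. All 20 genes of these groups had non-overlapping values between strains, as the rule that picked them required.

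**Figure D1:**
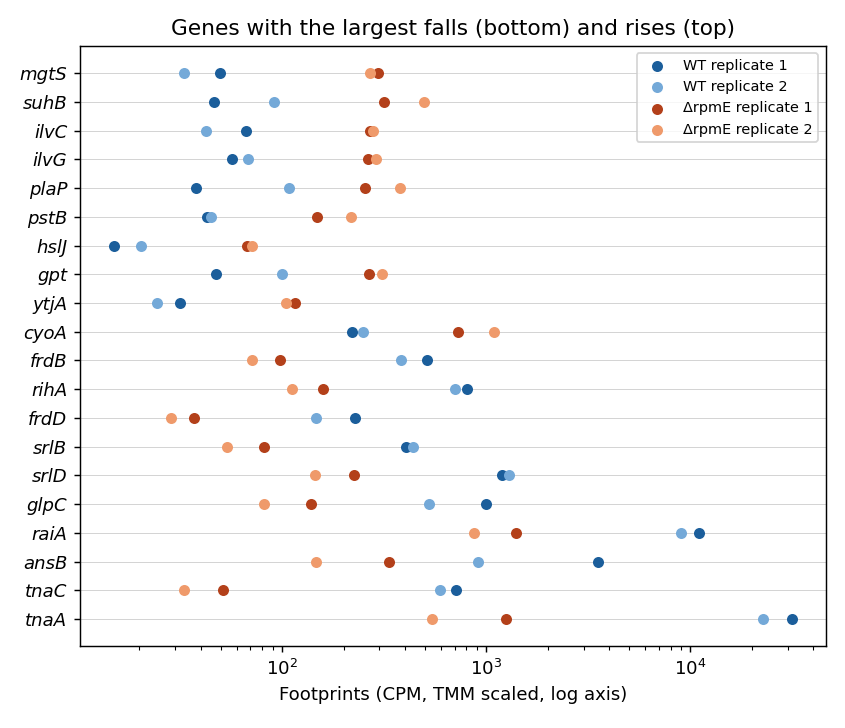
Footprints (CPM, TMM scaled, log axis) of the 20 tested genes with the largest rises and falls, with 1 point per library. Every ΔrpmE point lies to the right of both WT points for the 10 upper genes and to the left for the 10 lower genes. The rule that picked these genes required this. The gene ansB shows WT values of 3509 and 908.2.

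Genes listed in both libraries of only 1 strain lie outside the test and were given bounds, an approach chosen after seeing the data. The magnesium transporter gene mgtA was not listed in either WT library, where the listing rule allows at most 898 footprints, and carried 20092 and 23014 footprints in ΔrpmE. If that rule alone accounts for its absence, its scaled density was at least 50.4-fold higher in ΔrpmE. On the same basis pstS, for the phosphate-binding protein, was at least 17.4-fold higher and btsT, for a pyruvate transporter, at least 15.2-fold higher. Of 27 genes listed in both ΔrpmE libraries but not both WT libraries, 14 had every ΔrpmE value at least 2-fold above every WT value or bound. Of 506 genes listed in both WT libraries but not both ΔrpmE libraries, 31 differed that much the other way. Without WT replicate 2 these were 25 and 64. They included rpmE, the galactarate pathway gene garR, at least 7.72-fold lower, and the threonine dehydratase gene tdcB, at least 6.66-fold lower. These ratios carry no test.

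Among gene lists fixed before the data were examined, those for ribosome assembly and for branched-chain amino acids were higher in ΔrpmE relative to all genes by camera with a preset correlation, and neither passed otherwise (adjusted p = 0.966 for both with an estimated correlation). In the assembly list, 10 of 19 tested genes rose, 0 fell and 9 did not pass, and 12 rose when adjusted over the list alone. Without ΔrpmE replicate 1 the rises numbered 6 and without ΔrpmE replicate 2 they numbered 2. The cold-shock helicase gene deaD rose 3.48-fold (edgeR adjusted p = 0.00829), rimP by 1.24 ± 0.20 on the log2 scale (SE) and the GTPase gene obgE by 1.16 ± 0.20. The GTPase genes der and bipA rose by 1.09 and 1.17. The calls of obgE, der and bipA were lost without ΔrpmE replicate 2 (adjusted p = 0.0664, 0.0677 and 0.0635). The list had a median of 0.61 (camera, preset correlation, adjusted p = 0.00611). Of 6 branched-chain genes, ilvC, ilvB at 1.85 ± 0.21 and ilvN at 0.87 ± 0.20 rose and 0 fell, also when adjusted over the list alone. For ilvN the call was lost with either ΔrpmE library left out (adjusted p = 0.0549 and 0.132). The list median was 0.64 (camera adjusted p = 0.0174).

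Lists of sugar use and glycolysis genes were lower in ΔrpmE by camera with a preset correlation, and neither passed otherwise (adjusted p = 0.966 for both with an estimated correlation). Of 25 tested genes in the list of CRP-dependent sugar use, 16 fell, 1 rose and 8 did not pass, the same numbers as when adjusted over the list alone. The galactitol genes gatA, gatB, gatC, gatD, gatY and gatZ fell by 0.77 to 1.48, mglB and rbsB of galactose and ribose uptake by 1.46 and 1.42, and galP rose by 0.61. The call of galP was lost with either ΔrpmE library left out (adjusted p = 0.199 and 0.173) and that of gatY without ΔrpmE replicate 2 (0.0617). The calls of mtlD, galM and lacZ were also lost without ΔrpmE replicate 2, with values of -0.898, -0.615 and -0.769 against -0.989, -0.779 and -0.904. The numbers of falls and of rises in this list changed with some libraries left out. The list also holds tnaA, which degrades tryptophan and not sugar. Its median was -0.99 (camera adjusted p = 3.3e-08). In glycolysis 11 of 17 genes fell and 0 rose, against 13 falls and 1 rise when adjusted over the list alone. The falls numbered 7 without WT replicate 1, with 2 rises, 6 without ΔrpmE replicate 1 and 5 without ΔrpmE replicate 2. They included gapA at -1.16 ± 0.15, pykF at -1.04 ± 0.14 and pykA at -1.13 ± 0.17, with a list median of -0.52 (camera adjusted p = 0.0119). With the assembly and branched-chain lists, these were the only calls among 22 lists with at least 5 tested genes, although nucleotide synthesis also passed without WT replicate 2 or ΔrpmE replicate 1 (camera adjusted p = 0.00307 and 0.0145). The fry test, which asks whether a list moves one way, called 0 lists (lowest adjusted p = 0.137, with 7 lists at an unadjusted p under 0.05). With the estimated correlation camera called 0 of the 22, with 0 at an unadjusted p under 0.05. The 4 libraries leave only 2 residual degrees of freedom for that estimate, so a list that moved could fail as well.

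Few ribosomal protein genes passed the threshold. In the large subunit, 2 of 32 genes rose, 1 fell and 29 did not pass, and 0 passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 9, and DESeq2 called 5. In the small subunit, 3 of 21 rose and 0 fell, with 1 rise when adjusted over the list alone. The largest of these were rpsT at 1.17 ± 0.22 and rpmH at 0.92 ± 0.20 (SE, edgeR adjusted p = 0.0117 and 0.0195), and rpmH did not pass without ΔrpmE replicate 2 (0.0922). In the large subunit 6 genes passed without WT replicate 2, 1 without WT replicate 1 and 0 without ΔrpmE replicate 2, and in the small subunit 5 passed without WT replicate 2 and 1 without ΔrpmE replicate 2. Neither list passed camera (adjusted p = 0.912 and 0.654), and the large-subunit median of -0.03 had the opposite sign to its mean of 0.05. Among 9 hibernation and silencing factors, raiA fell, sra rose by 1.61 ± 0.18 and rsfS by 0.69 ± 0.19, and 6 did not pass. The call of rsfS was lost without WT replicate 1, ΔrpmE replicate 1 or ΔrpmE replicate 2 (adjusted p = 0.0736, 0.1 and 0.218). The list had 3 rises and 3 falls without WT replicate 2, 1 and 2 without WT replicate 1, and 1 and 1 with either ΔrpmE library left out. Adjusted over the list alone, 3 rose and 1 fell. Its median of 0.08 and mean of -0.14 also had opposite signs (camera adjusted p = 0.966).

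Neither the list of translation factors nor that of ribosome rescue passed camera (adjusted p = 0.373 and 0.414). Of 15 translation factors, prfC, for release factor RF3, rose by 1.59 ± 0.27, prfA, for the stop codon release factor RF1, by 1.02 ± 0.19 and lepA by 1.23 ± 0.29. For prfB, for release factor RF2, the value was 0.63 ± 0.22 and did not pass (adjusted p = 0.0672). The initiation factor gene infC fell by 0.55 ± 0.14 and 11 did not pass (edgeR). Without ΔrpmE replicate 2 the calls of prfA, lepA and infC were lost (adjusted p = 0.0984, 0.0764 and 0.208), and that of infC also without ΔrpmE replicate 1 (0.144). Rises numbered 5 without WT replicate 2 and 1 without ΔrpmE replicate 2. The count was the same adjusted over the list alone. In the rescue list of 5 genes, arfA, for an alternative rescue factor, rose by 1.69 ± 0.21 and pth, for peptidyl-tRNA hydrolase, by 1.67 ± 0.21 (both adjusted p = 0.00469), while smrB, smpB and rnr did not pass. Adjusted over the list alone, or without WT replicate 2, 2 rose and 1 fell. That list's median of -0.23 was negative and its mean of 0.47 positive.

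Respiratory genes went both ways. Of 29 genes, 9 rose, 12 fell and 8 did not pass, against 10 rises and 14 falls when adjusted over the list alone (camera adjusted p = 0.538). The cytochrome bo genes cyoA, cyoB, cyoC and cyoE rose by 0.83 to 1.95. The ATP synthase genes atpB, atpE, atpF and atpH rose by 0.68 to 0.84. The complex I genes nuoN, nuoM, nuoK and nuoH fell by 1.09 to 1.26. In the tricarboxylic acid cycle, 5 of 14 genes fell, led by gltA at -1.43 ± 0.16 (SE), mdh at -0.63 and fumA at -0.84. The only gene to rise was sdhC, at 0.88 ± 0.22, and adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.456; edgeR for genes). In nucleotide synthesis, 7 of 16 rose and 2 fell, with guaB at 1.16 ± 0.19, pyrF at 1.79 ± 0.33 and purA at -0.91 ± 0.14, against 9 and 2 adjusted over the list alone. That list did not pass camera (adjusted p = 0.0722) but did with the replicate number as a block (0.0176), without the first 50 codons (0.0463), without WT replicate 2 (0.00307) and without ΔrpmE replicate 1 (0.0145). Of 6 aromatic amino acid genes, aroH, aroB and aroC rose by 1.29, 0.76 and 0.61, also adjusted over the list alone (camera adjusted p = 0.373). Without ΔrpmE replicate 1 the respiratory list had 6 rises and 6 falls, the tricarboxylic acid list 1 fall and the aromatic list 1 rise. Without ΔrpmE replicate 2 these were 3, 3, 1 and 1, and nucleotide rises were 3, against 13 without WT replicate 2. Nucleotide falls numbered 1 with either ΔrpmE library left out, and tricarboxylic acid rises 2 without WT replicate 1 and 0 without ΔrpmE replicate 2. Calls lost without ΔrpmE replicate 2 were those of cyoC, atpB, atpE, atpF, atpH, nuoK, mdh, fumA, sdhC, aroB and aroC. Those of atpF, atpH, mdh, fumA, aroB and aroC were also lost without ΔrpmE replicate 1, and those of mdh and atpE without WT replicate 1.

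Stress lists other than SOS held changes in both directions, where 499 of all 1469 genes passed. In the RpoS list, osmY at 1.61 ± 0.18, osmB at 1.57 ± 0.22 and katE rose, bolA fell and 10 of 14 did not pass, and adjusted over the list alone 4 rose and 1 fell. In the heat shock list, grpE fell by 0.94, htpX and ftsH rose and 13 of 16 did not pass. Adjusted over the list alone, 1 rose and 1 fell. Of 6 cold shock genes cspC fell by 1.26 ± 0.15 and cspE rose by 0.89 ± 0.19, also adjusted over the list alone. Among 15 genes of OxyR and SoxRS, katG fell by 1.71 ± 0.33, trxC and acrA rose and in all 2 rose and 4 fell, by either adjustment. The 8 tested SOS genes held 0 changes by edgeR, by either adjustment, and led with ssb at -0.45 ± 0.16 (adjusted p = 0.0749). At an unadjusted p under 0.05 edgeR and DESeq2 each gave 1 SOS gene, and DESeq2 called 0 after adjustment. Without ΔrpmE replicate 2 the calls of katE, bolA, grpE, htpX, ftsH, trxC and acrA were lost (adjusted p between 0.0656 and 0.237). Those of katE, bolA, htpX, ftsH and acrA were also lost without ΔrpmE replicate 1 (0.0507 to 0.229), and those of ftsH and cspE without WT replicate 1 (0.0971 and 0.151). The RpoS list had 5 rises and 1 fall without WT replicate 1, 4 and 5 without WT replicate 2, and 2 and 0 with either ΔrpmE library left out. The heat shock list had 1 and 3 without WT replicate 1, 6 and 2 without WT replicate 2, 0 and 1 without ΔrpmE replicate 1, and 0 and 0 without ΔrpmE replicate 2. Cold shock genes gave 2 and 1 without WT replicate 1 and 1 and 3 without WT replicate 2. The OxyR and SoxRS list had 1 and 1 without ΔrpmE replicate 1 and 0 and 1 without ΔrpmE replicate 2, and the SOS list had 1 gene with either WT library left out.

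Envelope, secretion and synthetase genes also went both ways. In the envelope stress list, spy fell by 1.22 ± 0.16, cpxR fell, surA rose by 0.78 ± 0.16 and in all 2 rose and 3 fell of 16, against 3 and 3 adjusted over the list alone. Among 11 outer membrane genes, ompW fell by 2.15 ± 0.18, nmpC by 1.44 ± 0.15 and ompF by 0.91 ± 0.16, with 4 falls and 1 rise by either adjustment (camera adjusted p = 0.0773). Of 13 secretion genes, secG rose by 1.06 ± 0.18, secD rose, secB fell by 0.68 and in all 3 rose and 1 fell by either adjustment. Of 23 aminoacyl-tRNA synthetase genes, serS fell by 1.30 ± 0.17, lysU by 1.49 ± 0.23 and hisS rose by 0.82, with 2 rises and 3 falls, or 1 and 2 adjusted over the list alone. Without ΔrpmE replicate 2 the calls of cpxR, surA, secG, secD, secB and hisS were lost (adjusted p between 0.0578 and 0.192), and those of cpxR, secD and secB also without ΔrpmE replicate 1 (0.0678 to 0.135). The envelope stress list had 1 rise and 3 falls without WT replicate 2, 1 and 1 without ΔrpmE replicate 1, and 0 and 1 without ΔrpmE replicate 2. The secretion list had 1 and 0 without ΔrpmE replicate 1 and 0 and 0 without ΔrpmE replicate 2. The single outer membrane rise was lost without WT replicate 1 or ΔrpmE replicate 2, and the fall of ompC with either WT library left out. Synthetase genes gave 2 and 7 without WT replicate 1, 8 and 3 without WT replicate 2, and 0 and 2 without ΔrpmE replicate 2. Camera adjusted p for these lists and the stress lists, other than the outer membrane, lay between 0.449 and 0.966.

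A further 6 lists had under 5 tested genes. Both tested genes repressed by the zinc regulator Zur fell, znuA by 1.10 ± 0.19 and pliG by 1.03 ± 0.22 (SE, edgeR). In the phosphate starvation list pstB rose and phoU, at 0.20 ± 0.15, did not pass. The histidine gene hisI fell by 0.62 ± 0.19. In arginine, methionine and cysteine synthesis metK rose by 0.68 ± 0.18 and cysK, cysE and argG did not pass. The iron uptake gene exbB, at -0.40 ± 0.25, did not pass, and 0 flagellar genes were in the tested set. Without ΔrpmE replicate 2 none of znuA, pliG, hisI and metK passed (adjusted p = 0.0533, 0.131, 0.151 and 0.187), and hisI and metK also did not without ΔrpmE replicate 1 (0.288 and 0.0788) or WT replicate 1 (0.089 and 0.0506). The list of arginine, methionine and cysteine synthesis had 1 fall with either WT library left out.

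The second comparison asked whether footprints were placed differently along ORFs, since loss of ribosomes early in translation would lower the density further downstream. Footprints lay nearer the start of ORFs in ΔrpmE. The density from codon 51 to 5 codons before the stop, divided by that over codons 2 to 30, had a median log2 value of -0.16 and -0.18 in the WT libraries and -0.49 and -0.47 in ΔrpmE. The median change over 1268 ORFs of at least 100 codons was -0.31, a fall of 19.6%. The ratio fell in 336 ORFs and rose in 9 in edgeR's quasi-likelihood test of the segment by genotype interaction at an adjusted p of 0.05. Both ΔrpmE ratios lay below both WT ratios in 62.1% of ORFs and above both in 6.94%, where chance gives 16.7% each way. The count of 345 was 122 without WT replicate 1, 202 without ΔrpmE replicate 1 and 207 without ΔrpmE replicate 2. Rises numbered 3, 1 and 3 in these, and 17 without WT replicate 2.

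**Figure D2:**
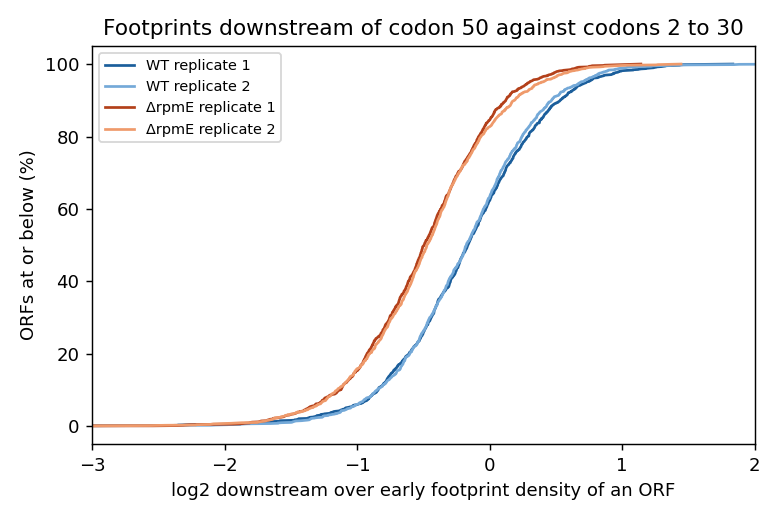
Cumulative share of 1268 ORFs (percent) by their log2 ratio of footprint density downstream of codon 50 to that over codons 2 to 30, with 1 line per library. Both ΔrpmE lines lie to the left of both WT lines through most of the range, with medians of -0.49 and -0.47 against -0.16 and -0.18.

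Among the 1268 ORFs tested, the largest fall of the ratio was in thrA, for aspartokinase and homoserine dehydrogenase, with a log2 change of -1.66 ± 0.17 (SE, edgeR adjusted p = 0.00217). Codons 2 to 30 held 2.83% ± 0.401 of its footprints in WT and 8.38% ± 0.188 in ΔrpmE (SD, n = 2 each). The lactate permease gene lldP changed by -1.64 ± 0.23, malK of the maltose transporter by -1.63 ± 0.20, the prophage gene yagN by -1.51 ± 0.13 and the lipoprotein gene slp by -1.47 ± 0.27. In malK the first segment held 6.47% ± 0.873 of footprints in WT and 16.5% ± 1.30 in ΔrpmE (SD, n = 2 each). The largest rises were in hemW at 1.24 ± 0.33, the folate gene folC at 0.92 ± 0.23, gpsA and tatB at 0.70 each and gph at 0.65, and each of these 5 lost its call with some library left out. Without WT replicate 1 these were hemW, folC, gpsA and gph (0.96, 0.93, 0.55 and 0.59), and without WT replicate 2 folC, gpsA and gph (0.91, 0.84 and 0.70). Without ΔrpmE replicate 1 they were hemW, folC, tatB and gph (0.91, 0.65, 0.75 and 0.71), and without ΔrpmE replicate 2 gpsA, tatB and gph (0.42, 0.66 and 0.59). In hemW the early segment held only 15 and 19 footprints in ΔrpmE, and codons 44 to 46, in neither segment, held 53.7% ± 1.38 of the gene's footprints in WT and 52.8% ± 6.36 in ΔrpmE (SD, n = 2 each). Of the gene lists, only that of ribosome assembly passed, with a smaller loss of the ratio than other ORFs, a median change of -0.16, 0 falls and 2 rises among 18 (camera adjusted p = 0.0398; adjusted p = 0.836 with an estimated correlation). Its camera adjusted p was 0.112 without WT replicate 1, 0.0638 without ΔrpmE replicate 1, 0.271 without ΔrpmE replicate 2, 0.0604 with the replicate number as a block and 0.16 with a downstream segment of codons 51 to 150. Some lists that did not pass had median changes as small, such as -0.11 for aromatic amino acids, -0.12 for translation factors and -0.13 for secretion. Others had larger losses, such as -0.46 for the tricarboxylic acid cycle. Across the 1268 ORFs the change of the ratio correlated with that of occupancy (Pearson r = 0.279, Spearman rho = 0.297). As the downstream segment is counted in both, part of this correlation may be built in. The assembly list lay higher in occupancy, so its value was not tested apart from that relation. Without WT replicate 2 the tricarboxylic acid and outer membrane lists also passed, with a larger loss (camera adjusted p = 0.0309 and 0.0155), and with an early segment of codons 6 to 30 the sugar use list did (0.0426).

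Averaged over the same 1268 ORFs, each scaled to its own mean from codon 51 on, density over codons 6 to 30 was 1.19 and 1.19 in the WT libraries and 1.50 and 1.47 in ΔrpmE, a rise of 24.3%. Over codons 31 to 50 it was 1.14 and 1.15 against 1.29 and 1.31, and over codons 1 to 5 it was 1.61 and 1.59 against 1.76 and 1.76. At codon 2, the start peak, the values overlapped, at 3.63 and 3.43 against 3.61 and 3.71. With 2 libraries against 2 the exact permutation test cannot give a two-sided p below 0.333, the value for each of these 3 regions, and it gave 0.667 for codon 2.

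At the end of ORFs the relative density was lower in ΔrpmE. The last 2 sense codons and the stop codon together had 2.37 and 2.15 in WT and 1.87 and 1.73 in ΔrpmE, a fall of 20.1% (two-sided exact permutation p = 0.333, the smallest possible). With positions shifted 1 codon downstream the stop codon peak left the region, which then held only the codons just before it. The values there were 1.21 and 1.22 against 1.10 and 1.01, a fall of 13.2%. The stop codon alone had 4.25 and 3.63 against 3.10 and 2.94. The spread between the WT libraries at the stop codon, an SD of 0.440, was larger than that between the ΔrpmE libraries, 0.114.

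**Figure D3:**
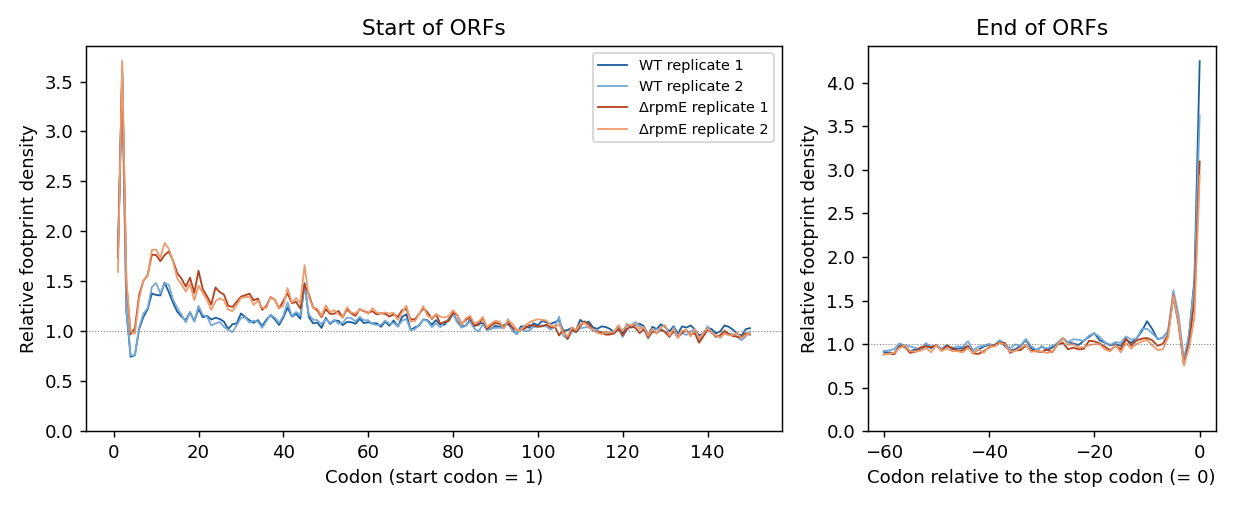
Mean footprint density by codon over 1268 ORFs, each scaled to its own mean from codon 51 on, with 1 line per library, from the start codon (left) and up to the stop codon (right). The ΔrpmE lines lie above WT over codons 6 to 30 (1.50 and 1.47 against 1.19 and 1.19) and below at the stop codon, and the peak at codon 45 comes mostly from hemW, without which that codon has 1.09 and 1.10 in WT and 1.22 and 1.28 in ΔrpmE.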

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

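Apart from the thinned WT libraries and the listing bounds, which were chosen after seeing the data, the alternatives were fixed before the data were examined. The 20 tested genes with the largest occupancy changes, the 5 largest falls of the downstream over early ratio and the 4 called gene lists kept their direction and their side of the threshold under every alternative in which they were tested, except that the list calls went from 4 to 0 when camera estimated the correlation, which lay between 0.119 and 0.439 for these lists. Of 83 named genes past the threshold for occupancy, 72 stayed past it under every alternative that kept all libraries and 50 also with each library left out. All 5 largest rises of the ratio lost their call somewhere. Without scaling beyond library size 451 genes were higher and 151 lower, since the median of all genes then moves to 0.28, and the log2 excess of rpmE in WT was 5.98 against 6.31. It was 6.40 without the first 50 codons and 6.24 to 6.37 with libraries left out, of which ΔrpmE replicate 1 gives no value. With no filter the set of genes was the same, so that setting tests nothing, and neither do minimums of 20 and 100 footprints per segment. DESeq2 called 317 higher and 278 lower, and 499 of these genes were shared with the 499 of edgeR. At an unadjusted p under 0.05 the count was 715 with edgeR and 704 with DESeq2.

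With the replicate number as a block, 771 genes differed (399 higher and 372 lower, 498 shared with the unblocked 499), and 14 ratios rose. The WT and ΔrpmE differences between replicates 1 and 2 correlated at r = 0.446 across genes, but 2 pairs cannot show that the numbers pair the samples. Leaving out 1 library gave 161 to 722 genes for occupancy (69 to 375 higher and 92 to 347 lower) and 122 to 334 for the ratio (119 to 317 falls and 1 to 17 rises), with a median change of -0.31 to -0.32 except -0.30 without ΔrpmE replicate 1. A lone library is then assumed to vary like the other group. The cause of the differences between these counts was not tested. The median change was -0.26 with an early segment of codons 2 to 50 and -0.27 with a downstream segment of codons 51 to 150. Rises numbered 2 with an early segment of codons 6 to 30 and 17 with the downstream segment of codons 51 to 150, and the cause was not tested.

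The log2 excess of ΔrpmE over codons 1 to 5 was 0.14. It was 0.10 with ORFs weighted by footprints, 0.16 with a 3 times higher minimum and 0.16 with capped positions. With positions shifted 1 codon upstream and downstream it was 0.22 and 0.10. The region then held codons 2 to 6 and codons 1 to 4, so other codons were averaged with the start peak. Weighting gave 0.28 over codons 6 to 30 against 0.31 and 0.17 over codons 31 to 50 against 0.19; why was not tested. The planned pseudocount alternative has no place with counts, and those on residues D, E and P and on codon occupancy were not run. Depth and the listing rule limit the test to genes with at least 1 footprint per codon in all libraries. The ΔrpmE libraries set this limit more often. They left out 506 genes that both WT libraries listed, in at least 1 library, against 27 the other way, among them mgtA.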

Other observations

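All tests in this part were chosen after the patterns they concern had been seen, and only the depth test was set before its own value was known. A list of 29 genes of anaerobic respiration was written after their values were seen, so its counts follow from that choice and test nothing. Of the 13 that all libraries listed, 10 were lower in ΔrpmE past the threshold and 0 higher, with a median log2 difference of -1.53, while 244 of all 1469 genes were lower. Between the WT libraries, 12 of 13 were higher in replicate 1, with a median log2 difference of 0.63. The nitrate reductase gene narG had 7179 CPM in WT replicate 1, 2017 in WT replicate 2, and 2161 and 1239 in ΔrpmE, and fdnG of formate dehydrogenase had 1577, 496.2, 471.6 and 222.7. Against WT replicate 2 alone the list was still lower in ΔrpmE, with a median of -1.15. The iron-sulfur regulator gene iscR went the other way, with 17.1 and 56.3 in WT and 58.0 and 82.4 in ΔrpmE.

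Besides the rises of the magnesium genes mgtS and corA and the bound for mgtA, the gene phoP, for a regulator that responds to magnesium, fell by 0.60 ± 0.16 on the log2 scale (SE, edgeR adjusted p = 0.0343), a call that was lost without scaling (-0.31, adjusted p = 0.203), without ΔrpmE replicate 1 (-0.56, adjusted p = 0.199) and without ΔrpmE replicate 2 (-0.65, adjusted p = 0.167). At known arrest sites the share of a gene's footprints was close in both strains. Codons 165 to 167 of secM, an arrest peptide regulated by export, were its 3 codons with the most WT footprints and held 32.3% ± 1.46 in WT and 30.9% ± 4.16 in ΔrpmE, and the stop codon of tnaC, codon 25, held 55.9% ± 1.32 and 52.4% ± 3.64 (SD, n = 2 each). The differences are smaller than the spread between the ΔrpmE replicates. Flanking sequence held 2.36% and 2.64% of footprints upstream in WT against 2.53% and 2.47% in ΔrpmE, and 2.62% and 2.56% downstream against 2.51% and 2.33%.

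The shift of footprints toward the start of ORFs was weighed against 3 explanations. Lower depth of the ΔrpmE libraries was argued against, since WT libraries thinned to 5869148 footprints had 1.16 and 1.20 over codons 6 to 30 and the lower ΔrpmE value stayed 0.270 above the higher of them. The state that set the WT libraries apart was also argued against, as their median log2 ratios differed by 0.012 against -0.31 between strains. A steady loss of ribosomes along the whole ORF predicts that the ΔrpmE over WT density keeps falling. The predicted change was -0.40 on the log2 scale from codons 101 to 150 to codons 251 to 300. It takes the whole fall between codons 2 to 30 and codons 101 to 150 as steady loss. A slower steady loss beside another early excess was not tested. In 554 long ORFs the ΔrpmE over WT density changed by 0.0495 instead (95% bootstrap interval over ORFs 0.0293 to 0.0709). That interval leaves out the spread between libraries, so it does not show a rise. Here each ORF was scaled to its own mean over codons 2 to 300, or 2 to 500 in the 158 longest ORFs. That mean includes the early excess of ΔrpmE, which by itself lowers the ΔrpmE values further on. The values are therefore not downstream losses on an absolute scale. At codons 251 to 300 the WT libraries had 0.9034 and 0.93, and the ΔrpmE libraries 0.8919 and 0.8999. In the 158 longest ORFs the log2 density of ΔrpmE over WT was -0.03 at codons 301 to 400 and -0.14 at codons 401 to 500. At codons 401 to 500 the WT libraries also lay apart, at 0.9055 and 0.9816, against 0.8428 and 0.8719 in ΔrpmE. A candidate explanation that remains is that the excess belongs to the first 100 codons or so. It could come through early loss of ribosomes, slower early elongation or a change in initiation, and these data do not separate them. A change in initiation that scaled all codons of an ORF alike would cancel in these ratios within ORFs. Whether cultures or handling differed between strains was not tested.

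The occupancy differences may in part follow a state of the culture and not bL31 itself. Across 1469 genes, which are not independent replicates, the difference between WT replicates 1 and 2 correlated with the difference between strains (Pearson r = -0.475, Spearman rho = -0.479). As both differences share the WT libraries, noise in WT replicate 1 alone could give an r down to -0.27. The WT difference was smaller, with an SD of 0.41 against 0.75 on the log2 scale. Which state this is, such as oxygen supply, density at harvest or growth rate, cannot be read from 4 libraries, and a direct effect of the deletion stays open, as untested.

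Footprints on rpmE in ΔrpmE replicate 1 have no settled origin. Their codon profile correlated with that of WT at r = 0.492, below the 2.5th percentile of 0.792 for WT footprints thinned to the same number, which covers counting error only. The 239 footprints occupy 119 positions, and with only 119 molecules copied by PCR the 95% interval for WT footprints is 0.277 to 0.625, so carry-over of WT reads stays open. Of the 239 footprints, 71.1% lay between the first 10 and last 10 codons (75.9% in WT), which argues against gene ends left in place by the deletion as their main source. No biological explanation was tested.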
